A study of Mus musculus with 18 samples.

How the data were processed

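Gene expression in the mouse cerebellum was measured with Affymetrix 3' expression arrays on 18 samples. The samples came from adult male mice of 3 genotypes, wild-type, apolipoprotein D (ApoD) knock-out and transgenic with ApoD over-expressed in neurons. Per the labels, 9 mice per genotype and treatment received 1 intraperitoneal injection of paraquat at 30 mg/kg in 200 µl of saline, or saline alone, and the tissue was taken 6 h later. RNA of 3 mice in equal amounts made up each pool, so that a group consisted of 3 arrays from separate mice, and the spread between arrays is a spread between pools. The titles name the arrays of mice injected with paraquat. The arrays whose titles do not name it were taken as saline from the protocol.

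The deposited values are on the log2 scale, 1 value per probe set and array. RMA, which includes background correction, quantile normalisation and median-polish summary, is named in the submitters' processing notes without a version. The scale was taken from the values, which ran from 3.13 to 14.9. No centring per gene was seen, and no ratio with a direction is involved. Which software release and which arrays were normalised together stays unknown. The deposited log2 medians were 7.11, 7.10 and 7.15 for replicates 1, 2 and 3 of wild-type saline and 7.13, 7.14 and 7.13 for knock-out saline. They were 7.14, 7.14 and 7.15 for transgenic saline and 7.12, 7.15 and 7.12 for wild-type paraquat. They were 7.13, 6.98 and 7.13 for knock-out paraquat and 7.14, 7.15 and 7.14 for transgenic paraquat. Scanner files were not used here, so background and scan batches were not examined. The number of arrays limits the precision. The half-width of the 95% confidence interval of a log2 fold change was 0.28 for the median gene in a comparison of 2 groups.

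The table held 22690 probe sets, of which 64 were controls. Gene symbols came from the platform annotation, which can be old. It gave 1 symbol for 20380 probe sets, several for 691 and none for 1555. Probe sets with several symbols or none were not used in the main analysis, and 0 symbols had to be updated through gene identifiers. The 20380 probe sets stood for 12393 genes, and each gene was represented by its probe set with the highest mean over all arrays. A gene was kept when its value reached the 40th percentile of the array on at least 3 arrays, which left 8320 genes. Genes were counted for which not all other probe sets shared the sign, among the named genes with other probe sets. It held for 0 of 31 under paraquat against saline in wild-type, 6 of 32 in knock-out, 4 of 17 in transgenic and 2 of 37 on average. It held for 8 of 11 in knock-out against wild-type under saline and 2 of 7 under paraquat, 4 of 26 and 15 of 49 in transgenic against wild-type, and 2 of 6 and 7 of 20 for the differences of the effect of knock-out and transgenic.

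Before the data were examined, the tests, the gene lists, the rule for naming genes and most alternatives were fixed. All 18 arrays were fitted together with 6 group means in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, which left 12 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and every adjusted p of a gene is limma's, two-sided. The comparisons were paraquat against saline in each genotype and averaged over genotypes, knock-out or transgenic against wild-type under each treatment, and the difference of the paraquat effect of knock-out or transgenic minus that of wild-type. A permutation test of 3 against 3 arrays cannot give a p below 0.1, so that single genes were not tested that way.

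Of 30 gene lists, 659 of 762 symbols were found on the array. Shifts of lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. The lists covered glucocorticoid response, immediate early genes, circadian clock, NRF2 targets, antioxidant enzymes, heat shock and unfolded protein response, amino acid response through ATF4, p53 targets, inflammation and cytokines, interferon response, cholesterol synthesis, lipid transport and metabolism, oxidative phosphorylation, cytosolic ribosome, proteasome and synaptic signalling. They also covered markers of granule neurons, Purkinje neurons, interneurons and Golgi cells, astrocytes and Bergmann glia, oligodendrocytes and myelin, oligodendrocyte precursors, microglia, endothelium, pericytes and smooth muscle, choroid plexus, meninges and fibroblasts, erythrocytes, leukocytes and neighbouring brain regions.

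The named genes are Apod, up to 12 called genes each way with the largest fold change and no overlap between the groups, the 10 smallest p-values where fewer than 10 genes were called, up to 4 called members of each list, the 4 leading members of each list whose test passed, and up to 12 genes each way called in a difference of effects. The genes on each side of Apod in the order of the mouse RefSeq annotation, 150 per side, were compared with 10000 random blocks of neighbouring genes in a permutation test, since a knock-out made in another strain can carry that strain's variants next to the deleted gene.

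The alternatives were no filter on low values, a filter at the array median, a further quantile normalisation, every probe set tested, an intensity trend with robust variance, array weights, a fit of only the groups compared, the replicate number as a block, and leaving out each array in turn. After the data were examined, fits without the second knock-out paraquat array, counts of list members without the third transgenic paraquat array, a replicate block within the transgenic arrays, and knock-out or transgenic against wild-type averaged over treatments were added.

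Replicate numbers recur in each group of the labels, without a statement that they mark a shared day or litter. Deviations from the group means over all genes tested correlated between transgenic saline and transgenic paraquat arrays of the same number at 0.16, 0.13 and 0.42, so the numbers were taken to pair the transgenic arrays from the data alone. The other comparisons of groups did not reach 0.1 in every pair. Wild-type came near, at 0.09, 0.15 and 0.34. There 5 of 6 arrays correlated best with their own number, against 3 of 6 in the transgenic. The block within the transgenic arrays was thus chosen on the same data to which it was applied, and calls it added rest on that choice.

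The calling step was tested on simulated data with the groups and the 8320 genes of the real arrays. Values were drawn as normal and independent, with a single SD per gene for all groups. Outlying arrays, unequal spread of the groups and correlation between genes were not simulated, so that the rates hold for such data only. For paraquat against saline in wild-type, 59.7% of genes changed by a log2 of 0.5, 97.0% of those changed by 1 and 100% of those changed by 2 were recovered, with 6 false calls. For the average over genotypes, 94.0%, 100% and 100% were recovered, with 9 false calls. For the difference of the paraquat effect between transgenic and wild-type, 20.9%, 86.6% and 98.5% were recovered, with 5 false calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.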

Results

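The arrays asked how the cerebellum of mice responds within 6 h to paraquat, a herbicide that generates superoxide, and whether apolipoprotein D (ApoD), a lipid-binding lipocalin, alters that response. Wild-type mice, ApoD knock-out mice and mice over-expressing ApoD in neurons received saline or paraquat, and each of the 6 groups was measured on 3 arrays of 3 pooled mice. After filtering, 8320 genes were tested. All arrays but 1 had a median log2 value between 7.10 and 7.15. The second knock-out paraquat array had a median of 6.98, an SD over probe sets of 2.06 against 2.20 to 2.28 elsewhere, and a mean correlation with all other arrays of 0.957 against 0.970 to 0.986. On this array the mean of the oligodendrocyte and myelin list was 10.1, the lowest of all.

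The transgenic arrays carried further technical signs that followed the replicate number. The dap spike-in control read 12.08 on the first transgenic saline array and 12.45 on the first transgenic paraquat array, and 10.52 to 11.15 on every other array. For pyruvate carboxylase, a labelling control, the 3' probe set exceeded the 5' probe set by 1.82 and 1.95 on the third transgenic saline and paraquat arrays, by 2.25 on the second knock-out paraquat array and by 2.63 to 3.16 elsewhere. The 18S ribosomal RNA control read 6.94 and 6.15 on the second and the third transgenic saline array and 6.33 and 6.20 on those of transgenic paraquat, against 7.30 to 8.42 on all other arrays. The first principal component held 32.8% of the variance and the second 26.9%.

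Apod itself read a log2 of 12.47, 12.38 and 12.54 on the wild-type saline arrays and 12.53, 12.68 and 12.76 on the wild-type paraquat arrays. The knock-out saline arrays read 8.40, 8.22 and 8.50 and the knock-out paraquat arrays 9.63, 9.83 and 9.16. The transgenic saline arrays read 12.25, 12.28 and 12.35, and the transgenic paraquat arrays 12.13, 12.29 and 12.32. Apod was lower in the knock-out under saline, with a log2 fold change of -4.09 (SE 0.13, adjusted p = 4.9e-14, n = 3 and 3 pools), and under paraquat, with -3.12 (SE 0.13, adjusted p = 8.7e-12). The knock-out saline mean of 8.37 ± 0.15 (SD) stood at the 44.7th percentile of the genes tested, although levels of different probe sets are not directly comparable. Whether the probes lie inside the deleted part of the gene is not known from the labels.

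Paraquat raised the Apod signal in the knock-out by a log2 of 1.16 (SE 0.13, adjusted p = 3.2e-05), from a linear mean of 333 to 757, against 5652 in wild-type under saline. In wild-type the paraquat effect on Apod was 0.19 (SE 0.13, adjusted p = 0.81), and in the transgenic -0.05 (SE 0.13, adjusted p = 1.0). The difference of the effect between knock-out and wild-type was 0.97 (SE 0.19, adjusted p = 0.49), and alternatives gave adjusted p from 0.0049 without the third knock-out paraquat array to 0.96. Apod was not higher in the transgenic than in wild-type. It differed by -0.17 under saline (SE 0.13, adjusted p = 0.48) and fell below wild-type by 0.41 under paraquat (SE 0.13, adjusted p = 0.040). Leaving out any 1 of the 6 arrays compared ended the call, at adjusted p from 0.054 to 0.12, as did quantile normalisation and no filter. Whether the transgene encodes a transcript that the mouse probes can read is not stated in the labels.

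**Figure D1:**
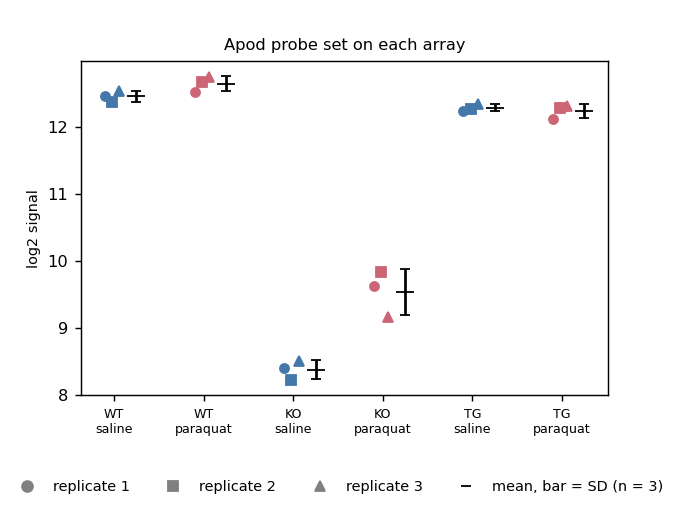
Apod signal on the log2 scale (vertical axis) for each array, by genotype and treatment (horizontal axis), with the mean ± SD of 3 pools per group. Means were 12.46 and 12.66 in wild-type, 8.37 and 9.54 in the knock-out and 12.29 and 12.25 in the transgenic under saline and paraquat.

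In wild-type cerebellum, paraquat raised most measured genes of the glucocorticoid response. Plin4, a coat protein of lipid droplets, rose by a log2 of 3.16 (SE 0.42, adjusted p = 1.3e-04), from 6.20 ± 0.34 to 9.36 ± 0.30 (mean ± SD, n = 3 pools each). Fkbp5, a co-chaperone that restrains the glucocorticoid receptor, rose by 2.50 (SE 0.24, adjusted p = 3.6e-06), which is 5.65-fold. Cdkn1a, which encodes the cell-cycle inhibitor p21, rose by 2.59 (SE 0.22, adjusted p = 5.3e-07), the siderophore-binding lipocalin Lcn2 by 2.46 (SE 0.20, adjusted p = 3.3e-07), and the kinase gene Sgk3 by 2.38 (SE 0.17, adjusted p = 7.9e-08). Of 34 measured members of the glucocorticoid response list, 26 rose and 0 fell, and 8 did not pass the test. Adjusted over the list alone, 29 rose and 2 fell. Its median log2 fold change was 0.90 (camera adjusted p = 1.4e-50). Other members that rose were Cebpd (1.84, SE 0.28), Angptl4, an inhibitor of lipoprotein lipase (1.78, SE 0.20), Zbtb16 (1.75, SE 0.33) and Sult1a1, a phenol sulfotransferase (1.77, SE 0.21).

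The metallothionein genes Mt2 and Mt1, whose products bind metals, rose by 1.33 (SE 0.16, adjusted p = 5.0e-05) and 0.80 (SE 0.12, adjusted p = 7.9e-04). With Msrb1, a methionine sulfoxide reductase gene (0.58, SE 0.10), they were the 3 of 24 antioxidant enzyme genes that rose, and 0 fell. The list shifted up with a median of 0.09 (camera adjusted p = 6.9e-04; adjusted p = 0.62 with an estimated correlation), and 4 rose adjusted over the list alone. Among 20 p53 targets, 3 rose and 1 fell, including Cdkn1a and Trp53inp1 (0.96, SE 0.18, adjusted p = 0.0057), around a median of 0.13 (camera adjusted p = 0.0062; adjusted p = 0.62 with an estimated correlation). Adjusted over that list alone, 6 rose and 1 fell. Adjusted over all genes without the second knock-out paraquat array, 5 rose and 1 fell. In the inflammation list 2 of 6 genes rose, Lcn2 and the NF-kappaB inhibitor gene Nfkbia (0.85, SE 0.15, adjusted p = 0.0024), with a median of 0.40 (camera adjusted p = 9.1e-06) and 4 higher adjusted over the list alone. Vcam1 stood at 0.43 (adjusted p = 0.20) and Il1r1 at 0.37 (adjusted p = 0.22). The glucocorticoid list shares 2 genes with the antioxidant list, 2 with the inflammation list, which are Lcn2 and Nfkbia, and 1 with the p53 targets. Most symbols of the inflammation list were not among the genes tested. Of 22 genes of the amino acid response, 2 rose, among them Chac1, which degrades glutathione (0.57, SE 0.14, adjusted p = 0.042), with a list median of 0.07 (camera adjusted p = 0.030; adjusted p = 0.73 with an estimated correlation) and 2 higher adjusted over the list alone.

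Outside these lists, further genes rose in wild-type under paraquat. They included Ada, encoding adenosine deaminase (1.96, SE 0.21), Nrros (1.71, SE 0.17), Lrg1 (1.59, SE 0.17), Polr3e (1.36, SE 0.13) and Smim3 (1.31, SE 0.13). The triglyceride lipase gene Pnpla2 rose by 1.32 (SE 0.14, adjusted p = 8.3e-06), the phagocytic receptor gene Mertk, which is in the glucocorticoid list, by 1.31 (SE 0.14), and the cold-inducible RNA-binding protein gene Cirbp by 1.12 (SE 0.14, adjusted p = 5.8e-05).

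Among the genes that fell was Fos, an immediate early transcription factor gene, which fell by 1.89 (SE 0.26, adjusted p = 1.6e-04), from 9.61 ± 0.14 to 7.72 ± 0.02, and Nr4a1 fell by 0.83 (SE 0.13, adjusted p = 0.0013). Of 22 immediate early genes 4 fell and 1 rose, Gadd45g (0.99, SE 0.10), around a median of -0.04 (camera adjusted p = 0.0497; adjusted p = 0.62 with an estimated correlation). Adjusted over that list alone, 4 fell and 2 rose, and with the replicate block over all arrays the list missed the threshold (camera adjusted p = 0.0528). The chemokine gene Cxcl12 fell by 1.11 (SE 0.15, adjusted p = 1.5e-04), the protease inhibitor gene Serpinb1a by 0.90 (SE 0.14, adjusted p = 6.2e-04), the endothelial receptor gene Tek by 0.83 (SE 0.18, adjusted p = 0.015) and Cx3cr1, a chemokine receptor of microglia, by 0.75 (SE 0.16, adjusted p = 0.015). Of 18 oligodendrocyte and myelin genes 2 fell, Sox10 (-0.62, SE 0.12) and Car2 (-0.60, SE 0.15), with a list median of -0.02 (camera adjusted p = 0.013; adjusted p = 0.73 with an estimated correlation) and 3 lower adjusted over the list alone.

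Among 33 heat shock and unfolded protein response genes 0 were called, yet the list shifted down with a median of -0.15 (camera adjusted p = 8.4e-06; adjusted p = 0.62 with an estimated correlation), and 7 were lower and 1 higher adjusted over the list alone. Adjusted over all genes without the second knock-out paraquat array, 3 were lower and 1 higher. Hspa5, the main chaperone of the endoplasmic reticulum, stood at -0.53 (SE 0.17, adjusted p = 0.17) and Manf at -0.58 (SE 0.17, adjusted p = 0.11). The 12 interferon response genes (median -0.08, camera adjusted p = 0.0497) and the 18 Purkinje neuron markers (median -0.07, camera adjusted p = 0.040) also shifted down with 0 genes called. With an estimated correlation their adjusted p = 0.62 and 0.73.

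In total 166 of 8320 genes changed in wild-type under paraquat, 127 higher and 39 lower, and 34 of them by more than 2-fold. All 166 had values without overlap between the groups, a split that 10% of unchanged genes would show with 3 against 3 arrays. The same arrays selected these genes, so that this adds no support. At an unadjusted p under 0.05 there were 829. Leaving out 1 array lowered the count to between 82, without the first wild-type saline array, and 103, without the second wild-type paraquat array. The count was 353 without the second knock-out paraquat array, 849 in a fit of the wild-type arrays alone and 1059 with array weights. Chac1, Tek, Cx3cr1 and Car2 lost their call under at least 1 alternative, with adjusted p up to 0.19, 0.096, 0.13 and 0.17.

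**Figure D2:**
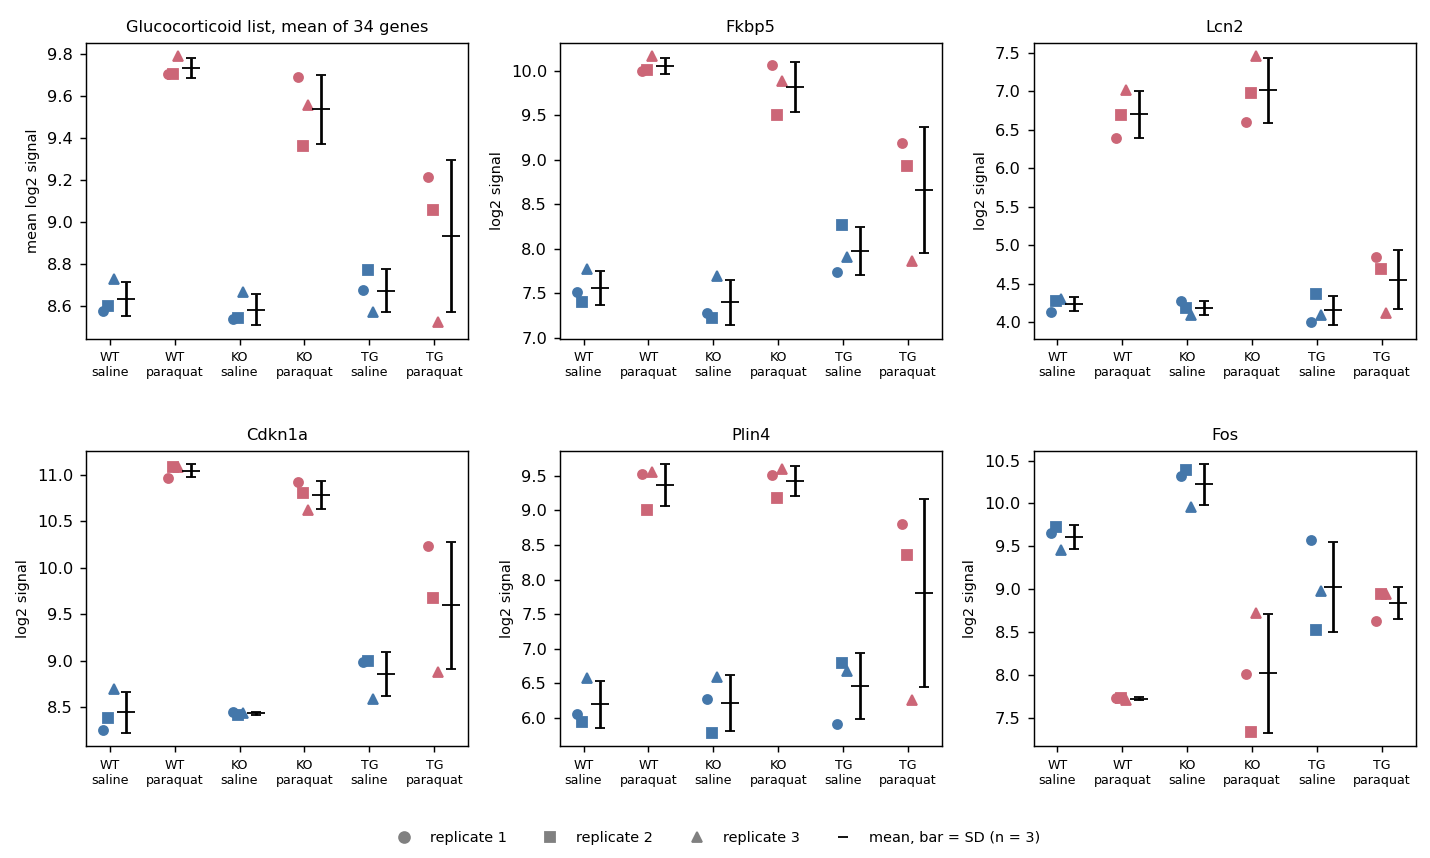
Log2 signal (vertical axes) of the mean of 34 glucocorticoid response genes, Fkbp5, Lcn2, Cdkn1a, Plin4 and Fos in each array, by genotype (horizontal axes), with saline in blue, paraquat in red and the replicate number as marker. Bars give the mean ± SD of 3 pools, which for Fkbp5 in wild-type were 7.56 ± 0.19 and 10.06 ± 0.09.

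The ApoD knock-out responded to paraquat with a rise of the same gene group. Plin4 rose by 3.20 (SE 0.42, adjusted p = 1.2e-04), Lcn2 by 2.83 (SE 0.20, adjusted p = 5.7e-08), Fkbp5 by 2.42 (SE 0.24, adjusted p = 7.3e-06), Cdkn1a by 2.35 (SE 0.22, adjusted p = 3.0e-06) and Sgk3 by 2.04 (SE 0.17, adjusted p = 5.8e-07), with n = 3 pools per group. Of the 34 glucocorticoid response genes 21 rose and 2 fell, Dusp1 (-0.79) and the receptor gene Nr3c1 itself (-0.53), which were named after their values were seen. Adjusted over the list alone, 26 rose and 2 fell. The list median was 0.74 (camera adjusted p = 9.6e-45). Members that rose included Map3k6 (1.77, SE 0.23), Sgk1, a kinase named after its induction by serum and glucocorticoids (1.40, SE 0.24), Mt2 (1.38, SE 0.16) and Cebpd (1.40, SE 0.28). In the inflammation list 2 of 6 genes rose, with a median of 0.36 (camera adjusted p = 4.8e-05) and 3 higher adjusted over the list alone. Of 24 antioxidant enzyme genes 3 rose, Mt1 (0.84, SE 0.12), Mt2 and Msrb1 (0.46, SE 0.10), around a list median of 0.01 (camera adjusted p = 0.0036; adjusted p = 0.87 with an estimated correlation), with the same 3 adjusted over the list alone, and the median was 0.08 without the second knock-out paraquat array. The 22 amino acid response genes had a median of 0.05 (camera adjusted p = 0.018; adjusted p = 0.87 with an estimated correlation) and 0 called in either way of adjusting.

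Fos fell by 2.21 in the knock-out (SE 0.26, adjusted p = 3.2e-05), from 10.22 ± 0.23 to 8.02 ± 0.70, and with it the orphan nuclear receptor genes Nr4a2, by 1.67 (SE 0.30, adjusted p = 0.0042), and Nr4a1, by 1.04 (SE 0.13, adjusted p = 1.0e-04). Cxcl12 fell by 1.35 (SE 0.15, adjusted p = 3.1e-05), Serpinb1a by 1.20 (SE 0.14), the hyaluronan receptor gene Cd44 by 1.24 (SE 0.17, adjusted p = 1.3e-04), Prrx1 by 0.95 (SE 0.13) and Cx3cr1 by 0.91 (SE 0.16, adjusted p = 0.0041). The neural progenitor transcription factor gene Sox2 fell by 1.07 (SE 0.24, adjusted p = 0.018) and Trim59 by 1.14 (SE 0.26, adjusted p = 0.021). Of the 3 other probe sets of Prrx1, 2 shared its sign. Without the second knock-out paraquat array Sox2 and Trim59 were at -0.67 (adjusted p = 0.053) and -0.71 (adjusted p = 0.073).

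Myelin and heat shock genes moved together with that array in the knock-out. Of 18 oligodendrocyte and myelin genes 3 fell, Car2 (-0.80, SE 0.15), Aspa, an enzyme of N-acetylaspartate breakdown (-0.78, SE 0.17), and Pllp (-0.64, SE 0.15), and 7 were lower adjusted over the list alone. Their median of -0.23 (camera adjusted p = 0.0036; adjusted p = 0.87 with an estimated correlation) was -0.10 with 2 genes lower when the second knock-out paraquat array was left out. Of 33 heat shock genes 2 fell, Dnajb1 (-0.73, SE 0.16) and Cryab (-0.53, SE 0.12), with 1 of 2 other probe sets of the same sign, and 6 were lower adjusted over the list alone. The list median of -0.27 (camera adjusted p = 2.6e-04; adjusted p = 0.87 with an estimated correlation) was -0.10 with 0 genes called without that array.

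All 188 genes called in the knock-out were without overlap, but the same arrays selected them. Of them 66 were higher and 122 lower, and 32 changed by more than 2-fold. At an unadjusted p under 0.05 there were 1484. The split depended on scaling, with 132 higher and 127 lower after quantile normalisation, and with 97 higher and 54 lower without the second knock-out paraquat array. The count was 44 in a fit of the knock-out arrays alone, 2173 with array weights, 63 without the second knock-out saline array, 66 without the first, 107 without the third and 614 without the third knock-out paraquat array. Cebpd, Msrb1, Aspa, Pllp, Dnajb1 and Cryab lost their call under at least 1 alternative, with adjusted p up to 0.060, 0.18, 0.11, 0.11, 0.12 and 0.25.

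The responses of wild-type and knock-out overlapped, and they share no arrays. Of the genes called in each, 89 were called in both, where 3.75 would be shared by independent draws. All 166 genes of wild-type had the same direction in the knock-out, with a slope of 0.86. Across all genes the effects correlated at r = 0.70 (rho 0.57), where genes are not independent replicates. For the difference between knock-out and wild-type, 148 genes had an unadjusted p under 0.05. Unchanged genes would give a share of 0.05, so these p-values run high and do not show an absence of effect. By limma the paraquat effect differed for no gene between knock-out and wild-type. Alternatives gave 0 genes as well, except 2 with array weights and 1 without the third knock-out paraquat array. The effect on Fkbp5 differed by -0.07 (SE 0.34). The median difference over all genes was -0.12, and -0.01 without the second knock-out paraquat array, so that values of single genes stand relative to this shift. Cd44 differed by -0.67 (SE 0.23, adjusted p = 0.87), Entpd7 by -0.62 (SE 0.18), Dbt by -0.68 (SE 0.23) and the transcription factor gene Nfia by -0.55 (SE 0.18), and 0 of 30 lists shifted.

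**Figure D3:**
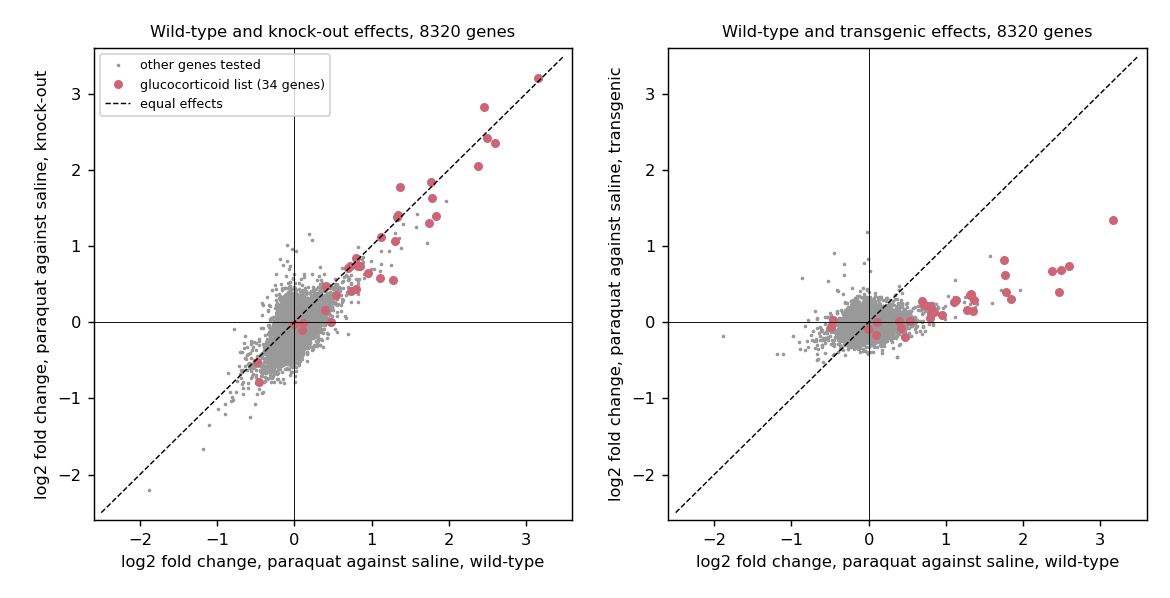
Log2 fold changes under paraquat of 8320 genes in the knock-out and in the transgenic (vertical axes) against those in wild-type (horizontal axes), with 34 glucocorticoid response genes in red and a dashed line of equality. Across genes r was 0.70 for the knock-out and 0.29 for the transgenic.

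In the ApoD transgenic no gene was called under paraquat by limma, and the glucocorticoid response genes showed smaller values. Fkbp5 had a log2 fold change of 0.69 (SE 0.24, adjusted p = 1.0), from 7.97 ± 0.27 to 8.66 ± 0.71, Plin4 of 1.34 (SE 0.42), Cdkn1a of 0.74 (SE 0.22), Sgk3 of 0.67 (SE 0.17) and Lcn2 of 0.40 (SE 0.20). As a group the 34 genes shifted up with a median of 0.22 (camera adjusted p = 3.0e-17; adjusted p = 0.24 with an estimated correlation), with 0 called and 2 higher adjusted over the list alone. The 3 transgenic pairs of the same number differed in the list mean by 0.54, 0.29 and -0.05, where wild-type gave 1.13, 1.11 and 1.06 and the knock-out 1.15, 0.82 and 0.89. The third transgenic arrays were those with the low pyruvate carboxylase difference.

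Choroid plexus genes, which come from the epithelium that makes cerebrospinal fluid, stood higher under paraquat in the transgenic. Folr1, a folate receptor gene, stood at 1.19 (SE 0.32), Sostdc1 at 0.90 (SE 0.30), Kl, encoding klotho, at 0.83 (SE 0.34) and Ttr, encoding the thyroid hormone carrier transthyretin, at 0.78 (SE 0.29). The 13 genes of the list shifted up with a median of 0.44 (camera adjusted p = 1.5e-18; adjusted p = 0.074 with an estimated correlation, and 0.017 with the replicate block within the transgenic arrays as well), with 0 called and 4 higher adjusted over the list alone. The 6 genes of the inflammation list had a median of 0.13 (camera adjusted p = 0.013; adjusted p = 0.24 with an estimated correlation). The 18 oligodendrocyte and myelin genes shifted down with a median of -0.22 (camera adjusted p = 2.5e-06; adjusted p = 0.59 with an estimated correlation), the 19 cholesterol synthesis genes with -0.10 (camera adjusted p = 0.0034; adjusted p = 0.65 with an estimated correlation) and the 33 heat shock genes with -0.08 (camera adjusted p = 0.044; adjusted p = 0.99 with an estimated correlation; 0.0521 with the replicate block over all arrays). In the inflammation, myelin, cholesterol and heat shock lists no gene was called, also when adjusted over the list alone.

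At an unadjusted p under 0.05 there were 118 genes in the transgenic, a share under 0.05, so p-values run high. Other settings also gave 0, except for 409 with array weights, 1 with a replicate block within the transgenic arrays, Folr1, and 6 without the third transgenic paraquat array. Those 6, named after their values were seen, were Plin4 (2.11, adjusted p = 0.0015), Cdkn1a (1.10, adjusted p = 0.0093), Fkbp5 (1.09, adjusted p = 0.014), Sgk3 (0.91), Sostdc1 (1.38) and Xdh, encoding xanthine dehydrogenase (1.31). Without that array the glucocorticoid list median was 0.40 with 4 genes called, the choroid plexus median was 0.67 with 1 called, the myelin median was -0.37 and the heat shock median -0.05.

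Without a block, the paraquat effect was smaller in the transgenic than in wild-type for 15 genes and larger for 0. With the replicate block within the transgenic arrays the difference was called for 26 genes. It was negative for 23, each with a smaller rise or no rise in the transgenic, and positive for 3. Of these, Fos fell less in the transgenic (-0.19, against -1.89 in wild-type). Kcne2 and Sostdc1 had values of opposite sign (0.58 against -0.86, and 0.90 against -0.45). Neither gene was called within either genotype in the fit without a block, and both were lower in the transgenic than in wild-type under saline. Lcn2 differed by -2.06 (SE 0.28, adjusted p = 0.0028), Cdkn1a by -1.86 (SE 0.31, adjusted p = 0.012), Fkbp5 by -1.81 (SE 0.34, adjusted p = 0.026), Sgk3 by -1.70 (SE 0.24, adjusted p = 0.0028) and Ada by -1.55 (SE 0.29, adjusted p = 0.026). Lrg1 (-1.34, SE 0.24), Nrros (-1.29, SE 0.24), Polr3e (-1.21, SE 0.18), Pnpla2 (-1.08, SE 0.20; the other probe set had the opposite sign), Cirbp (-1.05, SE 0.20), Smim3 (-0.99, SE 0.19), Mertk (-0.95, SE 0.19) and Gadd45g (-0.94, SE 0.14) followed, with Spns2 (-0.77) and Mrnip (-0.73), which the naming rule did not reach and which were added after their values were seen. Plin4 differed by -1.82 (SE 0.59, adjusted p = 0.51) and Fos by 1.70 (SE 0.36, adjusted p = 0.059, and 0.046 with the block).

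Of the 34 glucocorticoid response genes 5 had a smaller effect in the transgenic, and adjusted over the list alone 28 differences were negative and 2 positive, around a median difference of -0.79 (camera adjusted p = 5.5e-35; adjusted p = 0.078 with an estimated correlation). The replicate block within the transgenic arrays gave 11 smaller. With that block the adjusted p at an estimated correlation was 0.028 for the glucocorticoid list and 0.035 for the inflammation list. The inflammation list differed by a median of -0.23 (camera adjusted p = 9.8e-04; adjusted p = 0.078 with an estimated correlation) with 1 gene called and 2 adjusted over the list alone. Antioxidant enzyme genes differed by -0.13 (camera adjusted p = 0.0018; adjusted p = 0.73 with an estimated correlation), with 0 called, 3 smaller adjusted over the list alone, and 1 smaller with the block, Mt2 (-0.95, adjusted p = 0.17, and 0.0081 with the block). The p53 targets also differed by -0.13 (camera adjusted p = 0.034; adjusted p = 0.79 with an estimated correlation), with 1 called and 3 adjusted over the list alone. Among lipid transport genes, with a median of -0.10 (camera adjusted p = 0.021; adjusted p = 0.79 with an estimated correlation), 2 of 31 were called, Lcn2 and Pnpla2, and the same number adjusted over the list alone.

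Higher values in the transgenic difference came from choroid plexus genes, with a median of 0.46 (camera adjusted p = 2.0e-09; adjusted p = 0.21 with an estimated correlation), 0 called, 3 higher adjusted over the list alone, and 2 higher with the replicate block within the transgenic arrays. These were Kcne2, a potassium channel subunit gene, at 1.45 (SE 0.34, adjusted p = 0.14, and 0.0052 with the block), and Sostdc1 at 1.35 (SE 0.42, adjusted p = 0.45, and 0.031 with the block). Leaving out the third transgenic paraquat array gave a choroid plexus median of 0.70 with 1 called. The immediate early genes had a median difference of 0.16 (camera adjusted p = 0.030; adjusted p = 0.31 with an estimated correlation), with 1 gene called lower, Gadd45g, 2 higher and 2 lower adjusted over the list alone, and Fos higher with the block. The heat shock list had 0.12 (camera adjusted p = 0.0046; adjusted p = 0.79 with an estimated correlation), the interferon list 0.10 (camera adjusted p = 0.0029; adjusted p = 0.31 with an estimated correlation) and the Purkinje markers 0.03 (camera adjusted p = 0.021; adjusted p = 0.79 with an estimated correlation), each with 0 genes called and 0 adjusted over the list alone.

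At an unadjusted p under 0.05 the difference held 378 genes, a share under 0.05. The count of 15 was 26 with the replicate block within the transgenic arrays, with all 15 shared, 7 with the block over all arrays, 34 without the second knock-out paraquat array, 687 with array weights and 7 without the third transgenic paraquat array. Single arrays left out gave 4 without the second wild-type saline array, 5 without the second transgenic saline or the first wild-type paraquat array, 6 without the second or the third wild-type paraquat array, 7 without the first wild-type saline array, 9 without the second transgenic paraquat array and 10 without the third wild-type saline array. Lcn2, Sgk3, Polr3e and Gadd45g kept their call under every alternative, while the highest adjusted p of the other 9 genes named by the rule ran from 0.051 for Cdkn1a over 0.12 for Fkbp5 to 0.19 for Mertk. Across genes the transgenic effect correlated with that of wild-type at 0.29 and with that of the knock-out at 0.45. The lowest values on leaving out 1 array were 0.128 for wild-type, without the first transgenic paraquat array, and 0.172 for the knock-out, without the first transgenic saline array. Of the 166 genes called in wild-type 134 had the same direction in the transgenic, with a slope of 0.23.

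Averaged over the 3 genotypes, paraquat raised most glucocorticoid response genes and lowered several myelin and heat shock genes. Plin4 rose by 2.57 (SE 0.24, adjusted p = 7.2e-07), Lcn2 by 1.90 (SE 0.11, adjusted p = 1.9e-09), Sgk3 by 1.70 (SE 0.10, adjusted p = 1.6e-09) and Xdh by 1.23 (SE 0.16, adjusted p = 5.6e-05), with n = 9 pools per treatment. The averaged Apod effect of 0.44 (SE 0.08, adjusted p = 0.0016) came from the knock-out, at 1.16, with 0.19 in wild-type and -0.05 in the transgenic. Of the 34 glucocorticoid response genes 26 rose and 2 fell, around a median of 0.59 (camera adjusted p = 7.6e-48), and 28 rose and 2 fell adjusted over the list alone. In the inflammation list 3 of 6 rose, Lcn2, Nfkbia (0.57, SE 0.08) and the interleukin 1 receptor gene Il1r1 (0.33, SE 0.07, adjusted p = 0.012), with a median of 0.31 (camera adjusted p = 1.0e-05) and 4 higher adjusted over the list alone. In fits without a block, 6 list results of the series also passed with an estimated correlation. They were the glucocorticoid and inflammation lists in wild-type, in the knock-out and in this average. These lists share Lcn2 and Nfkbia, so that the inflammation list is not a separate result.

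Fos fell by 1.43 on average (SE 0.15, adjusted p = 2.6e-06), Nr4a2 by 1.09 (SE 0.17), Cxcl12 by 0.96 (SE 0.09, adjusted p = 5.0e-07), Sox2 by 0.77 (SE 0.14), Thbd, an endothelial anticoagulant receptor gene, by 0.71 (SE 0.10), Tek by 0.70 (SE 0.10) and Erbb3, whose other probe set had the opposite sign, by 0.68 (SE 0.13). Of 18 oligodendrocyte and myelin genes 7 fell and 0 rose, among them Ugt8a, which makes the galactolipids of myelin (-0.59, SE 0.15, adjusted p = 0.022), Car2 (-0.55, SE 0.09), Aspa (-0.46, SE 0.10) and Pllp (-0.43, SE 0.09). Adjusted over the list alone 7 fell as well, around a median of -0.15 (camera adjusted p = 1.2e-04; adjusted p = 0.72 with an estimated correlation), and without the second knock-out paraquat array 7 fell around a median of -0.10. Of 33 heat shock genes 8 fell, and 10 adjusted over the list alone, including Hspa5 (-0.44, SE 0.10, adjusted p = 0.012), Manf (-0.44, SE 0.10), Dnajb1 (-0.40, SE 0.09) and Creld2 (-0.39, SE 0.10), with a median of -0.17 (camera adjusted p = 6.8e-06; adjusted p = 0.72 with an estimated correlation). Without the second knock-out paraquat array 7 heat shock genes fell and 1 rose, around a median of -0.11.

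Smaller list shifts of the average were those of antioxidant enzymes, 3 of 24 higher with a median of 0.03 (camera adjusted p = 0.0026; adjusted p = 0.72 with an estimated correlation), of the amino acid response, 3 of 22 higher with 0.02 (camera adjusted p = 0.016; adjusted p = 0.72 with an estimated correlation), and of p53 targets, 3 of 20 higher and 2 lower with 0.04 (camera adjusted p = 0.023; adjusted p = 0.72 with an estimated correlation). Adjusted over each list alone these were 3 higher, 4 higher, and 6 higher with 2 lower. Leaving out the second knock-out paraquat array gave medians of 0.06 for antioxidant enzymes, with 4 higher, and 0.06 for p53 targets, with 6 higher and 2 lower. The 28 cytosolic ribosome genes had a median of 0.03 with 0 called either way (camera adjusted p = 0.023; adjusted p = 0.92 with an estimated correlation). Abca1, a cholesterol exporter gene, rose by 0.40 (SE 0.07, adjusted p = 0.0012), and Nqo1, an NRF2-driven quinone reductase gene, by 0.23 (SE 0.06, adjusted p = 0.027). In all, 407 genes changed, 167 higher and 240 lower, 17 by more than 2-fold, with 1498 at an unadjusted p under 0.05. Quantile normalisation gave 295 higher and 299 lower, and array weights 2263 genes. The count was 614 without the second and 657 without the third knock-out paraquat array, 261 without the second knock-out saline array and 270 without the first wild-type paraquat array. Ugt8a, Creld2 and Nqo1 lost their call under at least 1 alternative, with adjusted p up to 0.053, 0.060 and 0.073.

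Transgenic cerebellum under saline had lower levels of choroid plexus genes than wild-type. Kcne2 was lower by a log2 fold change of -2.15 (SE 0.24, adjusted p = 6.2e-05), at 5.19 ± 0.63 against 7.34 ± 0.10 (mean ± SD, n = 3 pools each), Sostdc1 of -2.10 (SE 0.30), Folr1 of -1.91 (SE 0.32), Kl of -1.88 (SE 0.34) and Ttr of -1.35 (SE 0.29, adjusted p = 0.0098). Of 13 choroid plexus genes 12 were lower, also adjusted over the list alone, around a median of -1.32 (camera adjusted p = 3.8e-16; adjusted p = 0.12 with an estimated correlation). The list mean was 6.62, 6.96 and 6.22 on the transgenic saline arrays, lowest on the third, and at least 7.78 in wild-type. Meninges and fibroblast genes were lower as well, 6 of 16, and 7 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 3.6e-07; adjusted p = 0.27 with an estimated correlation). Among them were the matricellular protein gene Ccn3 (-1.64, SE 0.16, adjusted p = 2.9e-05), the proteoglycan genes Ogn (-0.92, SE 0.14) and Lum (-0.70, SE 0.14), and Igfbp2 (-0.79, SE 0.16). The lysozyme gene Lyz1 was lower by -0.98 (SE 0.14), the interferon-induced Ifit3 by -0.91 (SE 0.15), Zfp932 by -1.38 (SE 0.16) and Crim1 by -1.35 (SE 0.21).

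Higher in the transgenic under saline were Rph3a, which encodes the synaptic vesicle protein rabphilin (1.34, SE 0.19, adjusted p = 6.7e-04), at 9.69 ± 0.17 against 8.35 ± 0.15, Pisd-ps3 (1.07, SE 0.11, adjusted p = 3.9e-05), Mgat3 (1.07, SE 0.20), the receptor tyrosine kinase gene Ret (0.81, SE 0.11) and the brain metallothionein gene Mt3 (0.76, SE 0.16). Gfap, the filament protein gene of astrocytes, was higher by 0.67 (SE 0.16, adjusted p = 0.016). The 18 oligodendrocyte and myelin genes shifted up with a median of 0.30 (camera adjusted p = 0.0021; adjusted p = 0.89 with an estimated correlation) and 0 called either way, and 2 were higher with the replicate block within the transgenic arrays, Gsn (0.58) and Pllp (0.38). Leaving out the second knock-out paraquat array, 4 were higher, and without the third transgenic paraquat array 1 was higher and 1 lower.

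Under saline 514 of the genes called were without overlap, but the same arrays selected them. In all 529 genes differed, 165 higher and 364 lower, 28 over 2-fold, and 1999 at an unadjusted p under 0.05. The count was 795 with the replicate block within the transgenic arrays, 964 for every probe set, 1163 after quantile normalisation, 1564 without the second knock-out paraquat array and 4112 with array weights. It was 108, 123 and 292 without the first, the second or the third wild-type saline array, and 1262, 144 and 238 without the first, the second or the third transgenic saline array, the first being that with the high dap control. Ttr and Gfap lost their call under at least 1 alternative, with adjusted p up to 0.075 and 0.091.

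Under paraquat the transgenic differed from wild-type in the glucocorticoid response genes and again in choroid plexus and meninges genes. Lcn2 was lower by -2.15 (SE 0.20, adjusted p = 1.8e-06), at 4.56 ± 0.38 against 6.70 ± 0.31, Sgk3 by -2.04 (SE 0.17, adjusted p = 6.1e-07), Ddit4, an inhibitor of mTOR signalling, by -1.76 (SE 0.33), Fkbp5 by -1.40 (SE 0.24, adjusted p = 9.0e-04) and Ada by -1.66 (SE 0.21). Of the 34 glucocorticoid response genes 23 were lower and 0 higher, and 28 lower and 1 higher adjusted over the list alone, with a median of -0.73 (camera adjusted p = 6.7e-11; adjusted p = 0.61 with an estimated correlation). Leaving out the third transgenic paraquat array gave 16 lower and a median of -0.55. Of 20 p53 targets 8 were lower, including Trp53inp1 (-1.21, SE 0.18), the cyclin gene Ccng1 (-0.97, SE 0.14; 1 of 2 other probe sets shared the sign) and the ribonucleotide reductase gene Rrm2b (-0.95, SE 0.16), with a list median of -0.25 (camera adjusted p = 0.0086; adjusted p = 0.85 with an estimated correlation) and 10 lower adjusted over the list alone. Of 22 amino acid response genes 7 were lower, including Chac1 (-0.93, SE 0.14) and Nupr1 (-0.75, SE 0.13), with a median of -0.20 (camera adjusted p = 0.020; adjusted p = 0.85 with an estimated correlation) and 8 lower and 1 higher adjusted over the list alone.

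Of 13 choroid plexus genes 8 were lower under paraquat, and 9 adjusted over the list alone, with a median of -0.70 (camera adjusted p = 2.2e-04; adjusted p = 0.77 with an estimated correlation). They included Calml4 (-1.23, SE 0.19) and the bicarbonate transporter gene Slc4a5 (-0.91, SE 0.20). The replicate block within the transgenic arrays gave 11 lower, and leaving out the third transgenic paraquat array 5. Of 16 meninges and fibroblast genes 7 were lower, and 8 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 2.2e-04; adjusted p = 0.61 with an estimated correlation), among them Ccn3 (-2.0, SE 0.16, adjusted p = 6.1e-07), Lum (-0.84, SE 0.14), Fmod (-0.84, SE 0.20) and Ogn (-0.76, SE 0.14). The amylase gene Amy1 was lower by -1.79 (SE 0.20) and Lyz1 by -1.11 (SE 0.14).

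Higher under paraquat in the transgenic were Rph3a (1.45, SE 0.19, adjusted p = 8.8e-05), Kazn (1.16, SE 0.15), Fos (1.12, SE 0.26, adjusted p = 0.0055), the potassium channel genes Kcna6 (1.00, SE 0.21) and Kcna2 (0.99, SE 0.18), Smad5 (0.96, SE 0.10, adjusted p = 1.3e-05) and Mt3 (0.81, SE 0.16). Of 18 oligodendrocyte and myelin genes 2 were higher, Sox10 (0.80, SE 0.12) and Fa2h (0.47, SE 0.14), also adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.014; adjusted p = 0.87 with an estimated correlation), and 4 were higher with the replicate block within the transgenic arrays. Leaving out the third transgenic paraquat array gave a median of 0.09 with 1 higher and 1 lower. With the replicate block within the transgenic arrays, the heat shock list (camera adjusted p = 0.040, against 0.065 without it; adjusted p = 0.89 with the block and an estimated correlation) had 4 genes higher and 3 lower, and 2 higher and 3 lower without it. The synaptic list (camera adjusted p = 0.012, against 0.058; adjusted p = 0.81 with the block and an estimated correlation) had 8 higher and 1 lower, and 2 higher and 1 lower without it. For the heat shock list without a block, leaving out the second knock-out paraquat array gave 6 higher and 4 lower. Leaving out the third transgenic paraquat array gave 6 higher and 3 lower for that list.

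Under paraquat 1578 genes differed, 386 higher and 1192 lower, with 1542 without overlap, 57 over 2-fold, and 2858 at an unadjusted p under 0.05. Quantile normalisation gave 832 higher and 1261 lower. The count was 2771 for every probe set, 4129 with array weights, 2823 without the second knock-out paraquat array, and 897 and 828 without the first or second wild-type paraquat array. Fa2h lost its call under at least 1 alternative, with adjusted p up to 0.11. The saline and paraquat comparisons share no arrays and had 409 called genes in common, where 100 would be expected of independent draws, 101 higher and 308 lower in both. Of the 529 genes called under saline 524 had the same direction under paraquat, and across genes r was 0.76.

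**Figure D4:**
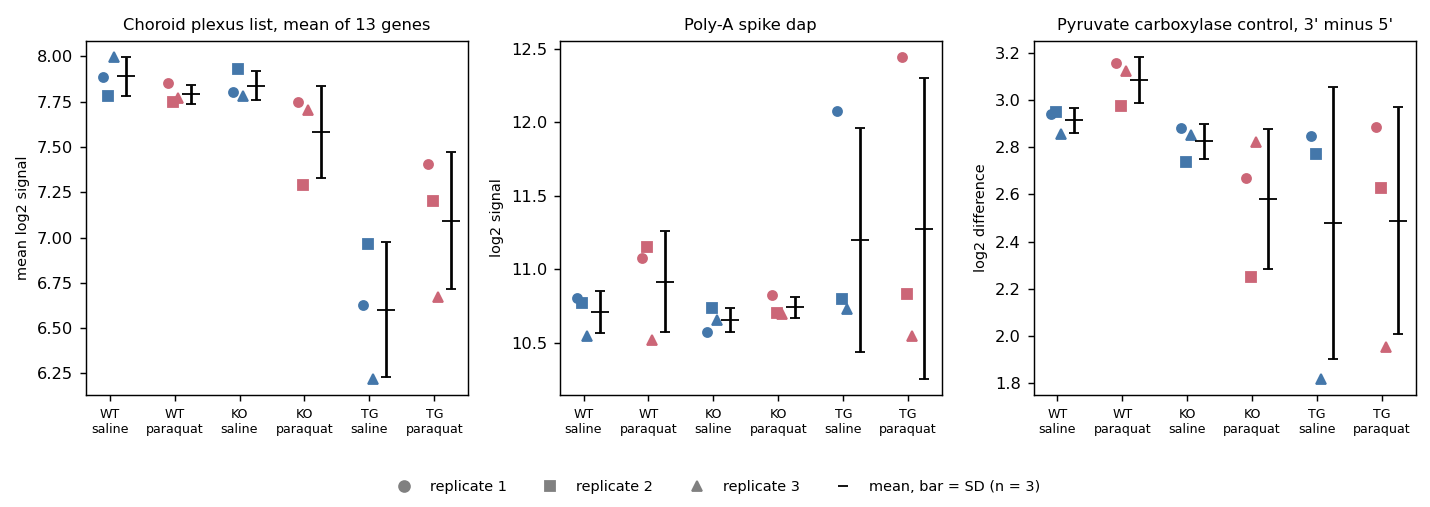
Mean log2 signal of 13 choroid plexus genes, log2 signal of the dap spike-in control, and log2 difference of the 3' and 5' probe sets of pyruvate carboxylase (vertical axes) in each array, by genotype (horizontal axes), with saline in blue and paraquat in red. The dap control read 12.08 and 12.45 on the first transgenic arrays.

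Knock-out and wild-type cerebellum differed in few genes. Under saline 2 genes were called by limma, Apod and Nfia, a transcription factor gene of the nuclear factor I family, which was higher by 0.91 (SE 0.13, adjusted p = 0.0038), at 7.83 ± 0.15 against 6.91 ± 0.17 (mean ± SD, n = 3 pools each). Other genes with small p-values were the deubiquitinase gene Otub1 at -0.78 (SE 0.16, adjusted p = 0.23), Arglu1 at 0.63 (SE 0.14, adjusted p = 0.43), Appbp2 at 0.59 (SE 0.14), Phxr4 at 0.83 (SE 0.19), Pigx at -0.41 (SE 0.10) and Hnrnpab at -1.06 (SE 0.27). The other probe sets of Otub1 and Arglu1 and 3 of 6 of Hnrnpab had the opposite sign, as did at least 1 for 8 of the 11 named genes of this comparison that had others. The 28 cytosolic ribosome genes shifted down with a median of -0.08 (camera adjusted p = 2.7e-04; adjusted p = 1.0 with an estimated correlation) and the 31 proteasome genes with -0.07 (camera adjusted p = 0.042; adjusted p = 1.0 with an estimated correlation; 0.0563 with the replicate block over all arrays), each with 0 called, also adjusted over the list alone. At an unadjusted p under 0.05 there were 129 genes, a share under 0.05, so p-values run high. The count was 4 for every probe set and with the replicate block, 3 without the second knock-out paraquat array, 108 in a fit of those 6 arrays alone and 241 with array weights. Nfia lost its call without the first wild-type saline array (adjusted p = 0.072) and without the first or second knock-out saline array (0.056 and 0.061).

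Under paraquat Apod was the 1 gene called between knock-out and wild-type. The developmental gene Crim1 stood at -1.21 (SE 0.21, adjusted p = 0.053), Nrros at -0.91 (SE 0.17, adjusted p = 0.053), Otub1 at -0.87 (SE 0.16, adjusted p = 0.053), and the calcium channel subunit genes Cacna2d1 and Cacna2d2 at -0.81 (SE 0.17, adjusted p = 0.12) and -0.75 (SE 0.14, adjusted p = 0.053), the latter with other probe sets of opposite sign. The median over all genes was -0.12, and -0.01 without the second knock-out paraquat array. No list shifted in this comparison. At an unadjusted p under 0.05 there were 1097 genes, and alternatives called 5 with the stricter filter, 4 with an intensity trend, 3 with the replicate block, 2 without the second knock-out paraquat array, 5 without the first wild-type and 12 without the first knock-out paraquat array, and 68 with array weights. Across genes the saline and paraquat differences of the knock-out correlated at 0.42.

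The chromosomal surroundings of Apod were examined in both genotypes. Of 54 tested genes among 150 on each side, 15 had an unadjusted p under 0.05 between knock-out and wild-type under paraquat (27.8%, against a median of 13.2% in random blocks, permutation p = 0.0090, adjusted p = 0.036), among them Nrros and Pigx. Under saline these were 2 (3.70%, against 1.30%, permutation p = 0.12, adjusted p = 0.24). For the transgenic they were 15 under saline (27.8%, against 23.7%, permutation p = 0.32, adjusted p = 0.40) and 20 under paraquat (37.0%, against 34.8%, permutation p = 0.40, adjusted p = 0.40). With 50 genes on each side the knock-out gave 10% under saline (permutation p = 0.040, adjusted p = 0.13) and 30.0% under paraquat (permutation p = 0.070, adjusted p = 0.13). The transgenic gave 45% under saline (against 23.5%, permutation p = 0.095, adjusted p = 0.13) and 40% under paraquat (against 35.3%, permutation p = 0.39). Without the second knock-out paraquat array the paraquat share of the knock-out was 9.26% (permutation p = 0.084).

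Of the 30 lists 14 shifted in no comparison of the fit without a block. Their lowest camera adjusted p over the comparisons was 0.27 for circadian clock genes, 0.38 for NRF2 targets, 0.10 for oxidative phosphorylation, 0.058 for synaptic signalling, which fell to 0.012 with the replicate block within the transgenic arrays and 0.0377 with that over all arrays, 0.10 for granule neurons, 0.19 for interneurons and Golgi cells, and 0.090 for astrocytes and Bergmann glia. It was 0.36 for oligodendrocyte precursors, 0.195 for microglia, 0.10 for endothelium, 0.53 for pericytes and smooth muscle, 0.54 for erythrocytes, 0.057 for leukocytes and 0.11 for neighbouring brain regions.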

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

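The tests that weigh an explanation for the 3 patterns below, the replicate block within the transgenic arrays, and the split with genotype and treatment means removed, were chosen only after the result was seen, while the tests of the difference, of the lists and of the other splits were set before.

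The paraquat effect differed between transgenic and wild-type for 15 genes, each with a smaller effect in the transgenic, by a test of the difference itself without a block. The log2 differences were -2.06 for Lcn2, -1.86 for Cdkn1a, -1.81 for Fkbp5, -1.70 for Sgk3, -1.55 for Ada, -1.34 for Lrg1, -1.29 for Nrros and -1.21 for Polr3e. They were -1.08 for Pnpla2, -1.05 for Cirbp, -0.99 for Smim3, -0.95 for Mertk, -0.94 for Gadd45g, -0.77 for Spns2 and -0.73 for Mrnip. By camera at the preset correlation 10 gene lists differed as well, but with an estimated correlation none of them passed, and with the replicate block added only the glucocorticoid (adjusted p = 0.028) and inflammation (adjusted p = 0.035) lists. Without the block the adjusted p was 0.078 for the glucocorticoid and inflammation lists, 0.21 for choroid plexus, 0.31 for immediate early genes and interferon, and 0.73 to 0.79 for the others. Their median differences were -0.79 for the glucocorticoid response, -0.23 for inflammation and cytokines, -0.13 for antioxidant enzymes, -0.13 for p53 targets and -0.10 for lipid transport and metabolism. They were 0.46 for choroid plexus markers, 0.16 for immediate early genes, 0.12 for heat shock and unfolded protein response, 0.10 for the interferon response and 0.031 for Purkinje neuron markers.

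The smaller glucocorticoid response in the transgenic arrays could come from 1 paraquat array without a response, from a compressed range of values, or from processing that followed the replicate number. Without the third transgenic paraquat array the difference in the list mean was -0.63 (SE 0.10), against -0.84 with all arrays, which argues against that array alone. The SD over probe sets of transgenic paraquat arrays was 0.977 times that of wild-type, where the slope of the effects was 0.23, but the normalisation evens out the spread of arrays, so this ratio cannot tell whether effects were compressed. The replicate block within the transgenic arrays gave 26 genes, 23 with a negative and 3 with a positive difference, and since it removes differences between numbers and not between genotypes, it cannot tell whether genotype or processing lies behind the difference. A weaker response in mice with the transgene and a weaker effective dose in those mice may both account for it, and the arrays hold no measure of dose.

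Lower choroid plexus genes in the transgenic arrays may reflect less choroid plexus tissue in the samples or lower gene activity per cell. Of the list members 92.3% were lower under saline and under paraquat alike and 0 were called higher, but this restates the pattern, and it cannot tell between the explanations. Processing by replicate number could also take part, as the list mean was lowest on the third array of each transgenic group. The second transgenic arrays, without the high dap control or the low pyruvate carboxylase difference but with a low 18S signal of 6.94 and 6.33, reached at most 7.202, against a lowest wild-type value of 7.75, so that processing stays open. A measure of tissue content independent of these genes was not available here.

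The Apod signal that rose with paraquat in the knock-out could come from 1 outlying array, from wild-type mice in the pools, or from transcript left outside the deleted part. Without the second knock-out paraquat array the log2 fold change was 1.02 (SE 0.12, adjusted p = 2.4e-04), which argues against that array alone. The level would need 6.91% (SD 2.81) of wild-type signal, where 1 wild-type mouse among 3 would give 33.3%, which argues against a mixed-up mouse. The saline level at the 44.7th percentile of tested genes cannot tell remaining transcript from background or cross-hybridisation, since levels of different probe sets are not directly comparable. The position of the probes in the deleted allele would decide between them.

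Regrouping the same arrays gave the following counts. For 3 against 3 arrays 10 splits cannot give a share under 0.05. The real count and the highest of the other splits were 166 and 0 for paraquat in wild-type, 188 and 0 in the knock-out, and 0 and 40 in the transgenic. They were 2 and 0 for knock-out against wild-type under saline and 1 and 0 under paraquat, and 529 and 0 and 1578 and 0 for transgenic against wild-type. The real split had the highest count alone, 1 of 10, in each of these except paraquat in the transgenic, where 10 of 10 reached its count of 0, and the 40 genes of another split point to structure among those 6 arrays.

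For the average over genotypes 1 of 100 splits reached 407 genes, with 7 as the highest other. With 100 splits the share cannot be lower than 1 of 100. Other splits also put the treatment effect into the spread, which lowers their counts. For the paraquat effect of knock-out minus wild-type 100 of 100 splits reached 0, with 15 as the highest other. For transgenic minus wild-type 10 of 100 splits reached 15 genes. The others exchange genotype labels, 1 fully (2610 genes) and 2 and 6 in part (up to 22 and 1169), and carry the genotype difference. The 42 splits without exchange gave 0. With genotype and treatment means removed first, 1 of 100 splits reached 15 genes, with 0 as the highest other. Both put the effect tested into the spread of other splits, so chance is not excluded.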

How the results depend on the processing

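Among the alternatives, the replicate block within the transgenic arrays and the fits without the second knock-out paraquat array were chosen after the data were seen. Of 338 values of named genes other than Apod that were called, 202 stayed called under every alternative, and 0 called values changed sign. The alternatives lost and gained calls as follows, 35 and 0 with no filter, 1 and 5 with the stricter filter, 17 and 10 with quantile normalisation, 21 and 0 for every probe set, 5 and 4 with an intensity trend, and 2 and 93 with array weights. Fits of only the groups compared lost 43 and gained 23, the replicate block lost 13 and gained 5, fits without the second knock-out paraquat array gained 13, and the block within the transgenic arrays gained 12. Leaving out 1 array lost 593 of 2922 calls and gained 36, with fewer arrays in each fit. The precision is limited by 3 arrays per group, and low signal limits genes near background, of which the filter removed those under the 40th percentile.

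The counts of called genes moved most with array weights, to 1059 for paraquat in wild-type, 2173 in the knock-out, 409 in the transgenic and 2263 on average, to 241 and 68 for knock-out against wild-type under saline and paraquat, to 4112 and 4129 for the transgenic, and to 2 and 687 for the differences of effects of the knock-out and the transgenic. The cause was not tested. A fit of only the groups compared, which takes the spread from 6 arrays instead of 18, gave 849 for paraquat in wild-type, 44 in the knock-out and 108 for knock-out against wild-type under saline. The SD over genes of the difference between arrays of a group was at most 0.15 in wild-type saline and 0.13 in knock-out saline. It was at most 0.18 in wild-type paraquat, 0.36 in transgenic saline, 0.33 in transgenic paraquat and 0.40 in knock-out paraquat. The spread shared by all groups averages over these, so that counts of called genes are not directly comparable between genotypes. Without the second knock-out paraquat array, which correlated least with the others, 353 genes were called for paraquat in wild-type, 614 on average, 3 for knock-out against wild-type under saline and 2 under paraquat, 1564 and 2823 for the transgenic under saline and paraquat, and 34 for the difference of the transgenic effect. Testing every probe set gave 4 and 2 for knock-out against wild-type under saline and paraquat, 964 and 2771 for the transgenic and 23 for the difference of its effect, with more features tested. Quantile normalisation gave 1163 for the transgenic under saline and 2 for knock-out against wild-type under paraquat, where the stricter filter gave 5 and the intensity trend 4, and the cause was not tested.

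The replicate number as a block over all arrays gave 4 and 3 genes for knock-out against wild-type under saline and paraquat and 7 for the difference of the transgenic effect. Of the list shifts it ended 3, with adjusted p of 0.0528 for immediate early genes in wild-type, 0.0521 for heat shock genes in the transgenic and 0.0563 for proteasome genes in knock-out against wild-type under saline, and it added synaptic genes in transgenic against wild-type under paraquat (0.0377). It gave 158, 170, 0 and 401 for paraquat in wild-type, knock-out, transgenic and on average. Of 6 arrays the number that correlated best with the array of their own number was 5 for paraquat in wild-type, 0 in the knock-out and 3 in the transgenic, 3 and 0 for knock-out against wild-type under saline and paraquat, and 4 and 4 for the transgenic. The pairs correlated at 0.09, 0.15 and 0.34 for paraquat in wild-type and -0.09, -0.28 and -0.12 in the knock-out. They correlated at -0.11, 0.09 and 0.13 for knock-out against wild-type under saline, and 0.32, -0.11 and 0.37 for the transgenic. Under paraquat these were -0.00, -0.20 and 0.04, and 0.08, 0.13 and -0.02. The block within the transgenic arrays gave 1 gene for paraquat in the transgenic, 795 for transgenic against wild-type under saline and 26 for the difference of the effect, 3 of them positive and 23 negative, and changed the count of no other comparison by more than 1.5 times. Of the list shifts at the preset correlation it changed 0 calls beyond the 2 given under transgenic against wild-type with paraquat. With an estimated correlation it added choroid plexus genes for paraquat in the transgenic and the glucocorticoid and inflammation lists for the difference of the effect.

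Apod in the transgenic against wild-type under paraquat was -0.41 (adjusted p = 0.055) with no filter, which tests more genes, and -0.38 (adjusted p = 0.12) after quantile normalisation, where the cause was not tested. Leaving out any 1 of the 6 arrays compared, so fewer arrays, also ended that call. The difference of its paraquat effect between knock-out and wild-type was 0.94 (adjusted p = 0.0057) with array weights, and the cause was not tested. Of 51 list shifts 6 held with an estimated correlation, which allows for genes that move together, and 20 with fry. Next to Apod, with 50 genes on each side and so fewer genes, 10% passed between knock-out and wild-type under saline and 30.0% under paraquat, and 9.26% passed under paraquat without the second knock-out paraquat array.

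Leaving out each array in turn gave 82 to 103 genes for paraquat in wild-type, 63 to 614 in the knock-out, 0 to 6 in the transgenic and 261 to 657 on average. It gave 1 to 2 for knock-out against wild-type under saline and 1 to 12 under paraquat, 108 to 1262 and 828 to 1301 for the transgenic, and 0 to 1 and 4 to 22 for the differences of effects. The Apod effect of paraquat ran from 0.14 to 0.25 in wild-type, from 1.02 to 1.35 in the knock-out, from -0.083 to 0.013 in the transgenic and from 0.39 to 0.50 on average. Against wild-type Apod ran from -4.15 to -4.01 in the knock-out under saline and from -3.26 to -2.93 under paraquat, and from -0.21 to -0.13 and -0.47 to -0.35 in the transgenic. The differences of its effect ran from 0.82 to 1.16 and from -0.30 to -0.18. Correlations of the paraquat effects across genes ran from 0.570 to 0.835 for wild-type and knock-out, from 0.128 to 0.326 for wild-type and transgenic and from 0.172 to 0.473 for knock-out and transgenic. No alternative had to be left out.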

Other observations

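Cirbp, whose product is induced by mild cold, also rose under paraquat in the knock-out, by 0.76 (SE 0.14, adjusted p = 0.0054), and stood at 0.07 (SE 0.14, adjusted p = 1.0) in the transgenic. On average over genotypes 1 of 14 endothelium markers rose and 4 fell, 2 and 6 adjusted over the list alone, and the list did not pass its test (camera adjusted p = 0.24). Of 13 microglia markers 0 rose and 2 fell, with either way of adjusting, and that list did not pass either (camera adjusted p = 0.19). The glucose transporter gene Slc2a1 rose by 0.56 (SE 0.11, adjusted p = 0.0025), while the tight junction gene Cldn5 fell by 0.42 (SE 0.09, adjusted p = 0.0093), the receptor gene Flt1 by 0.32 (SE 0.08, adjusted p = 0.020), Cx3cr1 by 0.61 (SE 0.09, adjusted p = 3.8e-04) and P2ry12, a purinergic receptor of resting microglia, by 0.44 (SE 0.11, adjusted p = 0.027). Eomes, a marker of unipolar brush cells, fell by 0.55 (SE 0.12, adjusted p = 0.0093). Flt1 and P2ry12 lost their call under at least 1 alternative, with adjusted p up to 0.054 and 0.066.

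Knock-out and wild-type were also compared with both treatments averaged, a comparison added after the data were seen. It called 15 genes, 3 higher and 12 lower, with 764 at an unadjusted p under 0.05. Besides Apod these were Nfia (0.64, SE 0.09, adjusted p = 0.0029), Appbp2 (0.57, SE 0.10), Arglu1 (0.51, SE 0.10), Otub1 (-0.83, SE 0.11, adjusted p = 0.0018), Crim1 (-1.01, SE 0.15), Pigx (-0.45, SE 0.07), Etv3 (-0.52, SE 0.09), Efcab14 (-0.65, SE 0.11) and the calcium channel subunit genes Cacna2d1 (-0.68, SE 0.12) and Cacna2d2 (-0.56, SE 0.10). The other 4 were Msi2 (-0.74), Basp1 (-0.49), St13 (-0.49) and Hnrnpab (-0.93), which lost their call without the second knock-out paraquat array. Without that array 16 genes were called, 11 of them shared. Pigx lies 28 genes from Apod. The other probe sets of Otub1, Arglu1 and Etv3 and 3 of 6 of Hnrnpab had the opposite sign under saline, as had those of Cacna2d2 under paraquat. For transgenic against wild-type with treatments averaged, 2610 genes were called, 895 higher and 1715 lower.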
